A study of Arabidopsis thaliana with 2 samples.

How the data were processed

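RNA from mature pollen of the Arabidopsis thaliana ecotypes Col-0 and Ler-0 was measured by RNA sequencing, with 1 library per ecotype. Per the labels' protocols, plants grew in long days, open flowers were vortexed in buffer to release the pollen, the suspension passed a mesh filter, and libraries were made with the ScriptSeq-v2 kit from total RNA depleted of rRNA. Per the submitters' processing notes, Subread and the build TAIR10 were used, with no version given for Subread. The rule for reads that align to several places, the use of strand, and whether reads or read pairs were counted are not given in the sources used here.

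The deposited values are FPKM, which the authors computed per gene, per the file headers, and each of the 2 tables lists the same 33322 nuclear loci with their coordinates. The product of FPKM and gene length (end minus start, introns included) was a whole multiple of a single step in 100% of values, within 0.01 of a whole number, so the reads behind each value were recovered. They summed to 76488187 in the Col-0 library and 88952509 in the Ler-0 library, and FPKM 1 in a gene of 1 kb corresponded to 76.5 and 89.0 reads. Because the length is the gene span, FPKM understates genes with long introns relative to others, equally in both libraries. TAIR10 is a Col-0 genome, so reads of Ler-0 that carry sequence differences had a poorer match to align to, and genes absent from that genome could not be counted. Loci were matched by locus tag to the TAIR10.1 annotation, which held 32834 of them, for symbols and products. Coordinates are those of the deposited tables, on TAIR10.

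The planned analysis assumed FPKM without counts. With reads recovered, exact 95% Poisson intervals were added to FPKM and exact binomial (Clopper-Pearson) intervals to ratios of FPKM between the libraries. Intervals and detection floors (3 reads, or 0.0392 FPKM in Col-0 and 0.0337 in Ler-0 for a gene of 1 kb) cover counting error only, since amplified reads are not independent molecules. There are no replicates, so no difference between the ecotypes has a replicate check and no p-value was computed. A ratio compares these 2 libraries, in which ecotype, plants, collection and library preparation vary together.

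The main measure was the log2 ratio of FPKM + 1, Ler-0 over Col-0, less its median of 0.06 over the 6656 genes at FPKM 1 or more in both libraries. A pseudocount of 1 understates the ratio of genes with low FPKM. Genes at FPKM 1 or more in either library are called expressed, and a gene was counted as apart at 4-fold, a centred log2 ratio of at least 2 either way. For each gene list, the median over expressed members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists outside percentiles 2.5 to 97.5 are said to stand apart, as a description of these libraries, and lists with under 5 expressed members are given by values. These rules, 10 lists of 189 genes, and the groups taken from the annotation (transposable element genes, cytosolic ribosomal protein genes and microRNA loci) were fixed before the data were examined. A list of LTR retrotransposon families and the lists of mitochondrial and chloroplast genes were not analysed here.

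The genes named were set by rule. Among genes at FPKM 10 or more in either library, leaving out structural RNA loci and transposable element genes, these were the 12 with the highest and the 12 with the lowest centred ratio. To them were added the 10 genes of highest mean FPKM, the 5 highest and 5 lowest expressed transposable element genes, the 2 highest and 2 lowest expressed members of each list, and the AGO, DCL, RDR and MIR845 loci. Genes named outside this rule, which were chosen after their values were seen, are marked where they appear. Near-identical copies were sought with BLAST 2.17.0 against all listed loci (at least 95% identity over at least 50% of the gene). The rule reads the gene's own length, so a long gene that contains a match to a shorter locus counts as without a copy. Among genes named, AT3G47800, AT4G26960, AT3G32925, AT5G50562, AT5G50565, SUVH6, GEX2, DCL1, DCL2, DCL3, RDR1, AMS, DER2.1 and P58IPK overlap another locus, and LHCB1.1 and LHCB1.2 have a near-identical copy, so their reads are uncertain without a stated use of strand or of shared reads.

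The procedure was tested on simulated reads for Ler-0 against Col-0 over 33322 genes, 200 of them changed 8-fold. At the 4-fold rule 99% of raised and 33% of lowered genes were called, and 100% of both at a base FPKM of 10 or more. None (0) of 8308 unchanged expressed genes was called. These genes had the same rates in both simulated libraries with counting error alone, so this does not measure false calls from variation between plants or preparations. Of 100 unshifted lists of 20 genes 2 stood apart, and 100 of 100 did when shifted by 1 log2 unit. The lists were random draws of expressed genes, so they do not stand for genes that vary together. Alternatives covered the pseudocount, the filter, centring, quantile normalization, protein-coding loci alone and a 2-fold threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.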

Results

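Transcripts of mature pollen were compared between the ecotypes Col-0, the source of the reference genome, and Ler-0, another laboratory ecotype, in a series on small RNAs from transposons that are triggered by microRNA and on the response to genome dosage. Pollen holds a vegetative cell, which grows the pollen tube, and a pair of sperm cells. Each ecotype has 1 library, so no difference below has a replicate check. The libraries held 76488187 (Col-0) and 88952509 (Ler-0) reads over 33322 nuclear loci. FPKM was 1 or more at 7803 loci in Col-0 and 8415 in Ler-0, and 0 at 2360 and 1236 loci.

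The Ler-0 library held far more RNA of PEX11D, BGLU36 and BIP2 than the Col-0 library. PEX11D (AT2G45740, chromosome 2, 18839586 to 18841403), a peroxisome division factor, stood at 148 FPKM against 1.94, a ratio of 76.6 (95% interval 68.0 to 86.8). BGLU36 (AT1G51490), a beta-glucosidase relative, stood at 1328 against 45.1, a ratio of 29.4 (28.8 to 30.1). BIP2 (AT5G42020), an Hsp70 chaperone of the endoplasmic reticulum, stood at 161 against 4.44, a ratio of 36.3 (34.1 to 38.6). Of 9562 expressed genes, 329 were at least 4-fold higher in Ler-0 and 212 at least 4-fold higher in Col-0, while 7494 (78.4%) were less than 2-fold apart. Restricting the values to protein-coding loci and rescaling them gave 188 and 170.

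Other genes with the highest centred log2 ratios were the glycosyl hydrolase AT5G09700 (5.45, 131 FPKM in Ler-0 against 1.90), the leucine-rich repeat gene PIRL7 (4.91), the serpin SRP3 (4.90, 33.7 against 0.115), the glycosyl hydrolase GH9C3 (4.85, 31.2 against 0.0680) and the galactose mutarotase-like AT3G47800 (4.76). AT5G04347, of the self-incompatibility S1 family, reached 588 against 23.3 FPKM (4.54). The F-box associated genes AT2G18320 (4.73) and AT5G52080 (4.84) also belonged here, and the short AT5G52080 has 4 near-identical copies, part of AT2G18320 among them, so its reads are uncertain. AT5G28465 rested on 1 read in Col-0 and 273 in Ler-0, a ratio of 235 (41.8 to 9306).

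Several genes abundant in Col-0 pollen were almost without reads in the Ler-0 library. The uncharacterized gene AT1G34095 (chromosome 1, 12411670 to 12412514) had 147637 reads and 2287 FPKM in Col-0 against 184 reads and 2.45 FPKM in Ler-0, a ratio of 0.00107 (0.000922 to 0.00124). AT4G04077 stood at 910 against 1.58 FPKM, and AT4G04078, which overlaps it, at 233 against 0.630. The 3 SPRY-domain genes AT4G09200, AT4G09250 and AT4G09310 on chromosome 4 stood at 111, 102 and 109 FPKM in Col-0 and 0.212, 0.215 and 0.203 in Ler-0; they are near-identical, so reads may be split among them. The same caution holds for AT5G50562, AT5G50565 and AT5G50665 (141, 62.9 and 62.5 FPKM against 0.0650, 0.116 and 0.110) and for AT2G22340 (159 against 0.428). AT1G31990 (65.9 against 0.168) and AT4G26960 (93.2 against 0.852) had no such copy, though AT4G26960 overlaps another locus.

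**Figure D1:**
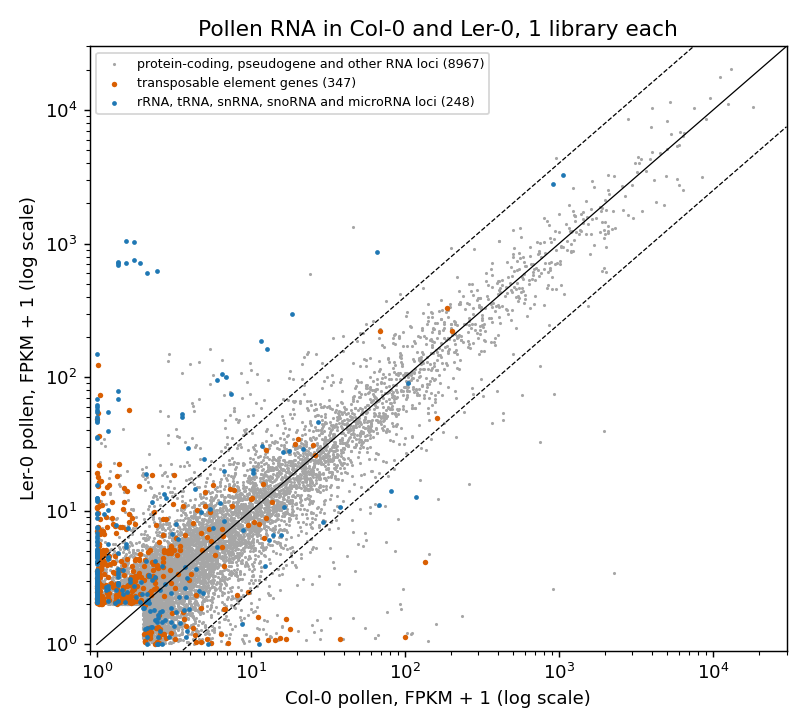
FPKM + 1 of each of 9562 expressed genes in the Col-0 (x) and Ler-0 (y) pollen libraries, both on log scales; the solid line marks equal values and the dashed lines 4-fold differences before centring. Transposable element genes (orange, 347) and structural and microRNA loci (blue) lie more often above the upper line than below the lower one.

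The most abundant transcripts were shared. RALFL9, a signalling peptide gene, stood at 18110 FPKM in Col-0 and 10613 in Ler-0, AT3G28750 at 13122 and 20318, AT2G41905 at 11094 and 17582, AT3G01240 at 12517 and 11076, and sks13 at 9535 and 12345. AT3G49540, AT2G47050 and AT1G78460 had centred log2 ratios of 0.41, -0.14 and 0.66, and AT5G54095 and the thioredoxin-like AT1G60740 had 1.05 and 1.31. The 100 genes with most reads took 50.9% of reads in Col-0 and 51.9% in Ler-0. Across expressed genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.87 and Spearman's rho 0.72.

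Genes of pollen tube growth and of the vegetative cell were expressed in both libraries. All 41 listed members were expressed, 15 with a centred log2 ratio above 0 and 26 below, and their median of -0.19 lay at percentile 11.5 of matched lists. The calcium-dependent kinase CPK34 stood at 461 FPKM in Ler-0 against 131 (1.75) and the receptor-like kinase PRK1 at 86.3 against 32.3 (1.33). The cellulose synthase-like CSLD1 stood at 233 against 526 (-1.24) and the pectin methylesterase VGDH1 at 2753 against 6057 (-1.20). The 14 sperm cell genes had a median of 0.13 (percentile 72.9); the sperm histone MGH3 stood at 138 in Ler-0, a ratio of 2.38 (2.30 to 2.47), and DAZ2 at 5.23 against 0.980, while GEX3 stood at 8.25 against 18.7 and GEX2 at 5.84 against 11.6.

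Among silencing and chromatin genes the widest gap was at MET1 (AT5G49160, chromosome 5, 19932230 to 19938369), the maintenance CG methyltransferase. It stood at 12.8 FPKM in Col-0 and 1.24 in Ler-0, a ratio of 0.0966 (0.0891 to 0.105). The list of DNA methylation and heterochromatin genes had 9 of 25 members expressed, with a median of -0.44 at percentile 7.06. Its other ends were SUVH6 at 4.61 in Ler-0 against 7.13, SUVH5 with a ratio of 1.39 (1.22 to 1.58) and NRPD1, of RNA polymerase IV, at 1.06 against 0.714. Of 22 small RNA silencing genes 3 were expressed, with AGO9 at 1.32 FPKM in Ler-0 against 4.28, AGO5 at 1.34 against 1.41 and HYL1 with a ratio of 2.16 (1.75 to 2.70). AGO1 (0.637 in Col-0, 0.859 in Ler-0), AGO2, AGO3, AGO4, AGO6, AGO7, AGO8, AGO10, DCL1, DCL2, DCL3, DCL4, RDR1, RDR2 and RDR6 stayed under FPKM 1 in both. Of these, RDR6 had 8 reads in Col-0 and 45 in Ler-0.

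The MIR845a and MIR845b loci on chromosome 4 had 0 reads in both libraries. Their detection floors of 3 reads were 0.490 and 0.400 FPKM in Col-0 and 0.422 and 0.344 in Ler-0. Of 177 primary microRNA loci 24 were expressed, with a median of -0.20 (percentile 8.50). MIR780 stood at 118 FPKM in Col-0 and 11.8 in Ler-0, and MIR408 at 10.9 and 29.5; both overlap another gene. MIR426 rested on 19 and 68 reads and MIR419 on 104 and 52. Of 17 imprinted or seed dosage genes 3 were expressed: PEG2 at 789 FPKM in Ler-0 against 582, a ratio of 1.36 (1.34 to 1.37), MEA with a ratio of 2.35 (2.05 to 2.70) and HDG9 with 25 reads in Col-0 and 749 in Ler-0.

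Transposable element genes were higher in the Ler-0 library as a group. Of 347 expressed, 271 had a centred log2 ratio above 0 and 76 below, with a median of 0.81 at percentile 100 of matched lists (random range -0.00 to 0.22). At least 4-fold differences were found at 61 higher in Ler-0 and 17 higher in Col-0, and their share of all reads was 0.741% in Ler-0 and 0.481% in Col-0. AT5G26618 stood at 123 FPKM (18529 reads) in Ler-0 against 3 reads in Col-0, AT1G46120 at 72.5 against 0.0560 and AT2G29165 at 52.9 against 0.0158. AT5G26618 and AT2G29165 are near-identical to each other and to part of the longer AT1G46120, as are AT3G32080 (47.5 against 0.00822) and AT2G04330 (35.5 against 0.0291) to each other, so their reads are uncertain. In the other direction AT1G31210 stood at 99.6 in Col-0 against 0.127 and AT3G60565, its near-identical copy, at 133 against 3.14; AT3G32925 (36.9 against 0.0953), AT3G28153 (15.8 against 0.102) and AT5G59640 (14.5 against 0.125), which also has near-identical copies, followed. Over all 3787 loci above FPKM 0, most of them near silence, the median was -0.015, still at percentile 100.

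Structural RNAs took a larger share of the Ler-0 library. tRNA loci held 0.00273% of reads in Col-0 and 0.0656% in Ler-0, 24.1 times the share, snRNA loci 10.3 times and rRNA loci 3.09 times. snoRNA loci held 7.36 times the share, but the median of the 39 expressed loci was -0.71, with 5 at least 4-fold higher in Ler-0 and 3 in Col-0. The tRNA locus AT3G50505, chosen after its values were seen, had 3 reads in Col-0 and 6560 in Ler-0. Of the 329 genes at least 4-fold higher in Ler-0, 59 were tRNA loci and 9 snRNA loci. Near-identical copies were not sought for these loci, so the reads of any single locus are uncertain and the counts may hold shared reads. Without structural RNA and microRNA loci, a choice made after seeing the data, the counts were 254 higher in Ler-0 and 206 higher in Col-0.

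The list of NLR immune receptor genes stood apart in the other direction. Of 19, 9 were expressed, with a median of -2.12 at percentile 0; the median was -0.24 over all 19 without a filter and -0.79 with a pseudocount of 5. The 12 expressed genes annotated as the TIR-NBS-LRR family, a grouping made after seeing the data, had a median of -0.91 at percentile 0.02, with 8 below 0. Single genes went both ways: 4 of the 12 were at least 2-fold higher in each ecotype, and 3 were at least 4-fold higher in Ler-0 and 2 in Col-0. RPP13 stood at 0.674 FPKM in Ler-0 against 8.63, and RPP5, which has a near-identical copy, at 0.381 against 6.85. RPP1 had the reverse order, 19.0 in Ler-0 against 0.569, and RRS1 stood at 1.14 against 0.657. Poorer alignment of Ler-0 reads to the Col-0 genome could lower the counts of NLR genes and was not tested for them.

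Markers of green tissue were present in both libraries. Of 12 photosynthesis genes 10 were expressed, with a median of -0.54 at percentile 1.83. The most abundant was LHCB1.1, named after its values were seen, at 28.9 FPKM in Col-0 and 33.1 in Ler-0; RBCS1A stood at 1.66 FPKM in Ler-0 against 4.07, a ratio of 0.408 (0.341 to 0.487), RBCS1B 0.259 (0.199 to 0.335), RCA 1.83 (1.66 to 2.02) and LHCB1.2 1.36 (1.24 to 1.48). With a filter of FPKM 5 the photosynthesis median turned to 0.23 over 4 members, and with a pseudocount of 5 it no longer stood apart. Of 5 floral organ identity genes 2 were expressed, SEP3 with a ratio of 2.00 (1.67 to 2.41) and AP1 1.70 (1.47 to 1.96), and of 18 tapetum genes 1, EXL5, at 1.46 (1.21 to 1.75).

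Genes listed by product name as cytosolic ribosomal proteins, with 49 of 120 expressed, had a median of -0.21 at percentile 1.09. Names that give no compartment were kept, so the list may hold organellar members. SAC52 stood at 30.1 FPKM in Ler-0 against 9.60 and AT3G13120 at 5.78 against 2.16, while AT4G18100 stood at 0.745 against 3.58 and AT1G70600 at 0.367 against 2.52. With a filter of FPKM 5 the median turned to 0.58 over 9 members. Heat shock and dehydration genes, 9 of 16 expressed, had a median of 0.12 (percentile 53.1). BIP3 stood at 16.7 in Ler-0 against 0.204, HSP70B had a ratio of 1.97 (1.78 to 2.18), ERD10 0.481 (0.428 to 0.541) and HSP17.6II 0.459 (0.339 to 0.617).

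**Figure D2:**
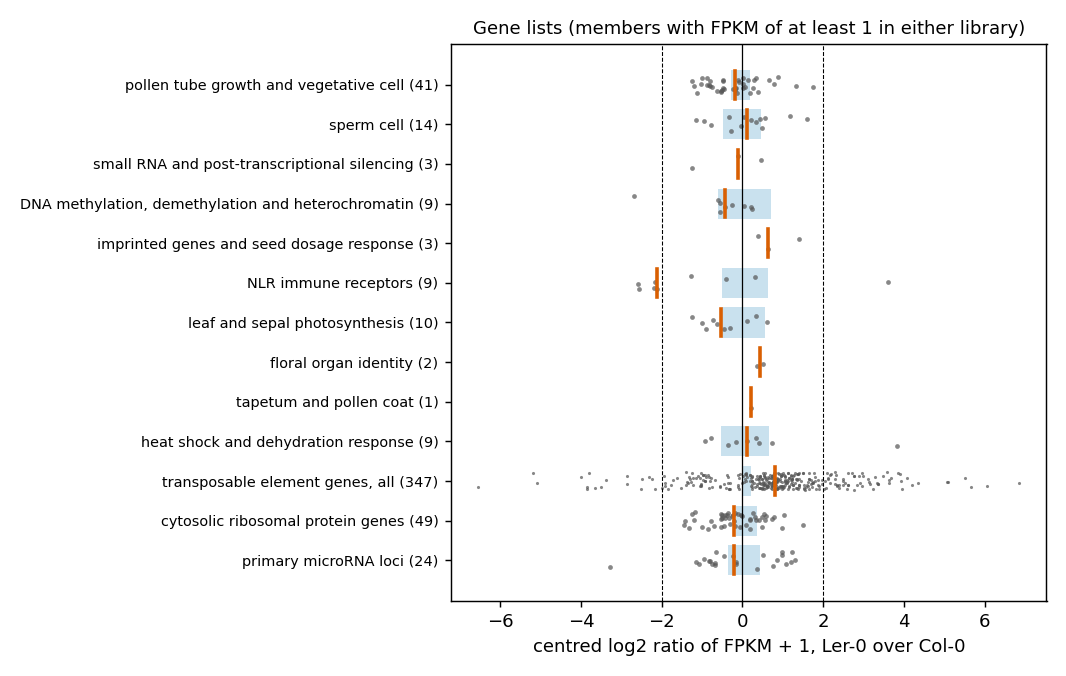
Centred log2 ratios (Ler-0 over Col-0, x) of the expressed members of each gene list (points, number in brackets), with the list median (orange) and the central 95% of medians of matched random lists (blue, for lists of 5 or more). Transposable element genes (0.81) lie above their range, and NLR (-2.12), photosynthesis (-0.54) and ribosomal protein genes (-0.21) below theirs; dashed lines mark 4-fold.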

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

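The restriction to loci other than structural RNA was chosen after seeing the data; the other alternatives were set beforehand. The numbers of genes at least 4-fold higher in Ler-0 and in Col-0 (329 and 212) became 750 and 580 with a pseudocount of 0.1 and 125 and 77 with 5. These pseudocounts widen or shrink the ratios of low genes. At a 2-fold threshold, which only moves the cut, the counts were 1079 and 989. Protein-coding loci alone, rescaled to the same total, gave 188 higher in Ler-0; 185 of the 329 are protein-coding. At the 4-fold threshold the share of such genes that were higher in Ler-0 was 60.8%, and it ran from 52.5% (protein-coding only) to 65.6% (centring on genes at FPKM 10 or more).

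Of the 4 lists that stood apart, 3 changed sign under an alternative. The ribosomal protein median turned to 0.58 (percentile 93.1) and the photosynthesis median to 0.23 at a filter of FPKM 5, over 9 and 4 members; the cause was not tested beyond the smaller membership. The transposable element median turned to -0.015 without a filter, over 3787 loci, but stayed at percentile 100. With a pseudocount of 5 the photosynthesis median was -0.19 (percentile 5.59) and no longer stood apart. NLR genes stood apart under each scaling, pseudocount and filter run, but their median ran from -0.24 over 19 members without a filter, through -0.79 with a pseudocount of 5, to -3.33 with a pseudocount of 0.1. The transposable element median was 0.28 with a pseudocount of 5 and 1.63 at a filter of FPKM 5. Lists that did not stand apart, or had too few members, also changed sign. These were microRNA loci (0.35) and sperm genes (-0.041) at a filter of FPKM 5, and, without a filter, microRNA loci (0.0033), heat shock (-0.14), floral identity (-0.035), tapetum (-0.043), imprinted (-0.0003) and small RNA silencing genes (0.0098). Of 243 named genes under 8 alternatives, 4 passed 4-fold with a pseudocount of 0.1 only, 7 (MET1, AT5G59640 and 5 RPP genes) no longer did with a pseudocount of 5, and 0 reversed while past 4-fold. The alternative of protein-coding loci alone covered only the protein-coding genes among the 243. No paired analysis was possible because each ecotype has 1 library. A gene of 1 kb at FPKM 1 rests on 76.5 reads in Col-0, and shorter or lower genes on fewer, which limits ratios there.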

Other observations

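The themes and sets in this part were chosen after seeing the data. Tests chosen only after the result was seen are those on heat stress, on other tissue, on the alignment of Ler-0 reads, on pooled copies and on primer-site genes without a copy.

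Of 104 product families with 8 or more expressed members, 5 had medians above and 6 below the central 95% of matched lists. Chance gives 2.6 on each side if family members vary independently. Reads shared within a family, as may occur between the F-box associated AT5G52080 and AT2G18320, were not allowed for. Plant thionins, small cysteine-rich peptides, had a median of -1.42, with 12 of 15 below 0. The p24/GOLD family, receptors for cargo between the endoplasmic reticulum and the Golgi, had a median of 1.18, with 8 of 9 above 0 and 4 at least 4-fold higher in Ler-0. F-box associated genes had 1.01 (10 members, 4 of them at least 4-fold higher in Ler-0 and 2 in Col-0) and the family annotated as late embryogenesis abundant proteins 0.82 (5 of 8 above 0), while its hydroxyproline-rich relatives had -0.16 (12 members, inside the range).

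Genes of the endoplasmic reticulum stress response were higher in the Ler-0 library. The theme came from 10 genes seen near the top of the ranking, such as BIP1 (133 FPKM against 5.54), CNX1 (31.3 against 1.89) and DER2.1 (50.4 against 1.89), which are not independent evidence. Of 32 further genes of the response whose values had not been looked at, 24 were expressed, 20 of them above 0, 12 at least 2-fold and 9 at least 4-fold higher in Ler-0. The 9 were SDF2, CRT1A, CRT1B, PDIL1-1, PDIL1-2, P58IPK, SAR1A, UTR1 and BZIP60, the last a transcription factor of the response (39.6 against 8.03 FPKM). UGGT went the other way, at 0.424 against 6.35 FPKM, and IRE1A and IRE1B had ratios of 1.07 and 1.11.

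The 24 unseen genes had a median of 1.13, at percentile 100 of matched lists. They hold no BIP gene, so reads shared among the BIP genes could not account for them. BIP1, BIP2 and BIP3 were each higher in Ler-0, which reads passed among them would not give. All had 0 near-identical copies by the rule used here. Heat shock and dehydration genes without BIP3 had a median of -0.025 over 8 members, the highest at 0.73, which argues against a strong general heat or dehydration stress. Only 3 listed members, BIP3 among them, reached FPKM 5 in either library, with a median of 0.73. Most of the 8 were thus low, where the pseudocount shrinks ratios, so a weaker stress is not excluded. Photosynthesis members had a median of -0.54 over 10, the highest at 0.62, which argues against a large excess of green leaf or sepal tissue in the Ler-0 preparation. The 4 members at FPKM 5 or more in either library had a median of 0.23, so a small excess is not excluded. The 3 expressed floral identity and tapetum members (SEP3, AP1 and EXL5) had 0.36. Members under FPKM 1 went both ways, with AP3 at 40 reads in Col-0 and 4 in Ler-0 and AMS at 91 and 34, but CYP704B1 at 60 and 155 and EXL6 at 35 and 81, and these low genes do not decide on other floral or anther tissue. A response that differs between the ecotypes remains a hypothesis. Such tissue, a small excess of green tissue and a weaker heat or dehydration stress remain open with it. So do plants, collection and library, since each ecotype has 1 library.

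For the higher transposable element genes, subtracting the median FPKM of 18521 silent protein-coding loci (0.117 in Col-0, 0.150 in Ler-0) left a median of 0.84. A background this small could hardly move genes that reach FPKM 1, so the test speaks only against a uniform background of this size. Only 10 of the 347 genes had a protein-coding gene of FPKM 10 or more within 1 kb, and the other 337 had a median of 0.83. Leaving out 10 genes could hardly move the median. So few such neighbours argue against reads running in from them, while weaker or more distant genes were not examined. Genes without a near-identical copy had a median of 0.71 (206) and those with one 1.05 (141). The criterion set beforehand would read 0.71 as evidence against extra copies in Ler-0, but it was set aside after the value was seen, because the search covered only loci of the Col-0 reference and so does not measure copy number in Ler-0. Extra copies and ecotype cannot be told apart here. The larger share of structural RNAs in the Ler-0 library shows that the libraries also differed in make-up.

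The next count left out structural RNA and microRNA loci. A total of 75 genes stood at FPKM 10 or more in 1 library with over 50-fold fewer reads, relative to depth, in the other. Of these, 40 had the fewer reads in Ler-0 and 35 in Col-0, a ratio of 1.14. Not all were near silence there: AT3G28810, named after its values were seen, kept 38.9 FPKM in Ler-0, and PEX11D 1.94 in Col-0. The balance differed by type, with 30 against 16 for protein-coding genes and 7 against 18 for transposable element genes. Other RNA loci had 3 against 0 and pseudogenes 0 against 1. Neither the ratio nor this split decides whether Ler-0 reads failed to align, which would leave the 35 unaccounted for. A near-identical copy was found for 28% of them and 3% of 500 other genes at FPKM 10 or more, 9.33 times the share, which met the criterion set beforehand for reads moved between copies. Pooling each gene with its copies, a test added after that value was seen and given more weight because moved reads stay within the pool, left 20 of 21 genes at least 4-fold apart, in 11 of 12 groups of copies that share members, with RALFL11 the exception. This argues against moved reads for those 20, the other 54 had no copy over 50% of their own length, though AT1G46120 and AT2G18320 among them contain matches to shorter loci, and gene loss or sequence difference between the ecotypes stays open and untested.

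A hypothesis drawn from the series title and from what is known of miR845 was that transposable element genes near a primer binding site for tRNA-Met differ from others. The 42 expressed genes with a 12-base site within 2 kb on their strand, the only window run, had a median of 1.25 against 0.79 for the other 305, at percentile 100 of matched sets of transposable element genes (0.46 to 0.97). Among genes without a near-identical copy the medians were 0.95 (18 genes) and 0.68, and the 18 did not stand apart from matched sets of such genes (percentile 95.6, range 0.049 to 1.04), a test added after the result was seen. The site marks LTR retrotransposons, which were not separated from other elements, so the site may stand for the class of element.

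Genes at least 4-fold apart followed each other along the chromosome, counting the 9314 expressed genes other than structural RNA and microRNA loci, more often than shuffled calls gave: 42 consecutive pairs in the same direction, against a median of 11 and at most 28 in 10000 shuffles. Of the pairs 24 were higher in Ler-0 and 18 in Col-0, and 8 overlapped, so that reads of one could be counted for the other. The gap had a median of 1.79 kb but exceeded 10 kb in 13 pairs, and some pairs, such as AT4G09200 with AT4G09250, are near-identical copies. Shuffling ignored the type of locus. Transposable element genes were at least 4-fold higher in Ler-0 more often (61 of 347) than protein-coding ones (185 of 8692). The excess of pairs was not separated from this difference. Pairs included RPP2A with RPP2B and SAR1B with CRT1a, named after their values were seen.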
